A study of Mus musculus with 2 samples.

How the data were processed

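KAT8 CUT&Tag was carried out on mouse bone marrow-derived macrophages left untreated or stimulated with R848 for 2 h, with 1 library per group, per the labels. Grouping followed the treatment label of each sample. The deposited data were 1 narrowPeak list per library, called per sample rather than on pooled samples. The submitters' processing notes name Bowtie 0.12.8, MACS2 2.2.7.1, DiffBind and the mm10 build, with no role or order stated, and alignment, duplicate and caller settings are not given in the sources used here. Whether a control library entered peak calling is likewise not given, and none was analysed here.

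For each peak the authors deposited a score, a fold over background (a ratio), −log10 of the p-value, −log10 of the q-value and the summit position. The deposited score was 10 times −log10 p in all peaks, to within 1. The lowest deposited −log10 p was 2.01 in both lists, so the lists hold all peaks down to a p-value of about 0.01, and 36.3% of untreated and 41.1% of R848 peaks had a q-value of 0.05 or less. The narrowest peaks were 200 bp wide (20.8% and 23.4% of peaks). Every peak lay on a standard chromosome and no interval was repeated. Such a permissive threshold leaves many weak peaks whose presence in 1 list only can reflect the threshold, and a deeper library passes it at a lower fold.

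The files give no read counts. The summit pileup and the local background of each peak were solved from the fold, taken as (pileup + 1) / (background + 1), and the Poisson tail of the p-value, and came out whole within 0.05 for 99.998% of untreated and 99.996% of R848 peaks. The lowest background was 3.37 and 2.62 fragments, a ratio of 1.29, and 69.4% and 61.7% of peaks were at that background. The lowest pileup called was 8 and 7. The R848 library is thus the shallower by this measure.

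Peaks were compared by overlap of at least 1 bp, with bedtools 2.31.1 as a check of the interval code. Shares have 95% exact (Clopper-Pearson) binomial intervals. Random placements (100) kept each peak's chromosome and width and lay between the lowest and highest peak positions of the chromosome; assembly gaps were not excluded. Genes came from a RefSeq table of GRCm38.p6, the assembly of mm10, without strand, transcript starts or exons. The planned promoter windows at transcript starts were therefore replaced by windows of 1000 bp on either side of both ends of each of 21887 protein-coding genes, and the classes of location were reduced to near a gene end, inside a protein-coding gene, inside another gene and outside genes. A gene was given a peak where any base of the peak fell in its window, while a peak's class of location followed its summit, so a peak at the edge of a window can count for the gene and still be classed as away from gene ends. A gene-end peak can thus lie at either end of a gene; of genes of at least 3000 bp with a peak, 95.6% and 95.9% had it at 1 end only. Of the 3792 genes with a peak in both lists, 3537 (93.3%) had overlapping peaks. In the untreated list 1013 peaks, and in the R848 list 868, were assigned to several genes. Motif shares and GC and CpG content, which need the genome sequence, were not analysed here, nor was the window at the gene's own 5′ end.

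For each of 17 gene lists, members with a gene-end peak were counted per library and compared with 10000 random lists of the same size. The number of members with a peak in the R848 list only minus that in the untreated list only was set among 10000 random lists of genes with a peak in either library, matched on the tenth of the highest within-list rank of fold. Percentiles describe these libraries and are not p-values. Of 383 list members, 381 were found in the table; Mx1 and Mx2 were not. The genes named are the 10 with the highest fold among genes with a peak in 1 list only, per direction, and the 5 with the highest fold per list. From each gene list they are up to 4 members with a peak in 1 library only and up to 4 with peaks in both, by falling fold. Kat8, Tlr7, Tnf, Il6, Il1b, Ifnb1, Nfkbia and Spi1 are named whatever their values, as are the 3 peaks of 1 list only outside gene ends with the highest fold, per list. A few items that this rule selects are not reported here. Sample groups, gene lists, the rule for named genes, the overlap and window sizes and most alternatives were fixed before the data were examined; the gene-end windows and the alternatives named as added were not.

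The alternatives were −log10 q of at least 5 or 10, lists of equal length, overlap of 50% of each peak, summits within 250 bp, windows of 500 or 3000 bp, repeated intervals counted once and all sequences kept. Added after the data were seen were a q of 0.05, that threshold against any peak of the other list, untreated pileups scaled to the R848 background, windows over the whole gene and 1000 bp around it, and overlap with a peak of the other list outside the window counted as presence. The code was tested on simulated data for the comparison of the untreated and R848 lists, over 21887 genes. All 200 genes given a simulated peak were recovered, with 18 further genes called because they share windows with them. The simulated pair was the untreated list and a copy of it with those peaks added. Of 100 random lists drawn from the same genes as the reference lists, 2 fell outside the central 95%. This checks the code and does not show how clustered gene lists behave. In the test of pileups, 1000 of 1000 simulated values were recovered. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.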

Results

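KAT8 is a lysine acetyltransferase of the MYST family and the catalytic subunit of the MSL and NSL chromatin complexes. Its genomic positions were profiled by CUT&Tag, in which an antibody directs a transposase to cut and tag the DNA around the bound protein. The cells were primary mouse macrophages grown from bone marrow with 20 ng/ml M-CSF. One group was left untreated (1 library) and the other received 100 ng/ml R848, a small-molecule agonist of the endosomal receptor TLR7 in mice, for 2 h (1 library). The untreated list held 52001 peaks covering 17.8 Mb and the R848 list 44772 peaks covering 15.3 Mb, with a median width of 281 bp in both. Each peak carries the authors' own score, fold over background and significance, which are used here to describe, rank or filter peaks within their list. Fragment pileups and backgrounds solved from these values are also set side by side between the libraries, as a measure of depth. Folds and q-values given for both lists describe each list and do not measure a change, since depth and background differ. Read totals were not used here, and the genome-wide background recovered from the peak values was 3.37 overlapping fragments in the untreated library and 2.62 in the R848 library. Neither group had a replicate, so no difference below has a replicate check and none has a p-value.

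The comparison of the libraries asks which genes carry KAT8 peaks in resting macrophages and which carry them after TLR7 stimulation. Peaks at the ends of Relb and Rel, which encode NF-kB subunits, of Nfkbia, which encodes the inhibitor IκBα, and of Traf3, an adaptor of Toll-like receptor signalling, were present in both lists. Cxcl2, a neutrophil-attracting chemokine, Nfkb1, the precursor of an NF-kB subunit, and Socs3, a feedback inhibitor of cytokine signalling, had a peak in the R848 list only. Ripk1, a kinase of TNF receptor signalling, Ier5, an immediate early gene, and Ctsd, the lysosomal protease cathepsin D, had one in the untreated list only. Of 21887 protein-coding genes, 6301 (28.8%) had a peak within 1000 bp of either end of the gene in the untreated library and 5349 (24.4%) in the R848 library. Both lists had a peak at 3792 genes, against 1540 for independent lists of those sizes, and a further 2509 genes had one in the untreated list only and 1557 in the R848 list only. At 29 and 22 of these genes the peak reached across the edge of the window and overlapped a peak of the other list that lay outside it, which leaves 2480 and 1535.

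Genes with the most significant peaks were nearly all found in both lists. Among the 572 genes with an untreated peak of −log10 q of at least 10, 565 had a gene-end peak of any strength in the R848 list and 4 of the other 7 had an overlapping R848 peak just outside the window, and all 386 genes with an R848 peak of that strength had one in the untreated list. Across all peaks, 16096 untreated peaks (31.0%, 95% exact binomial interval 30.6 to 31.4) overlapped an R848 peak by at least 1 bp, and 16036 R848 peaks (35.8%, 35.4 to 36.3) overlapped an untreated peak. Randomly placed peaks overlapped the other list in 1.19% and 1.38% of cases. Intervals here and below cover counting error only. The shared part depended on strength: of untreated peaks with −log10 p up to 3, 10.4% were shared, and of those between 10 and 30, 94.3% were. In the R848 list the same bins gave 14.5% and 97.3%. Peaks of 1 list only numbered 35905 (untreated) and 28736 (R848), of which 8422 and 7900 reached a q of 0.05 and 14 and 1 reached a −log10 q of 10. A peak in 1 list only can therefore lie just under the calling threshold in the other library, and counts of such peaks at stricter thresholds are far smaller.

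**Figure D1:**
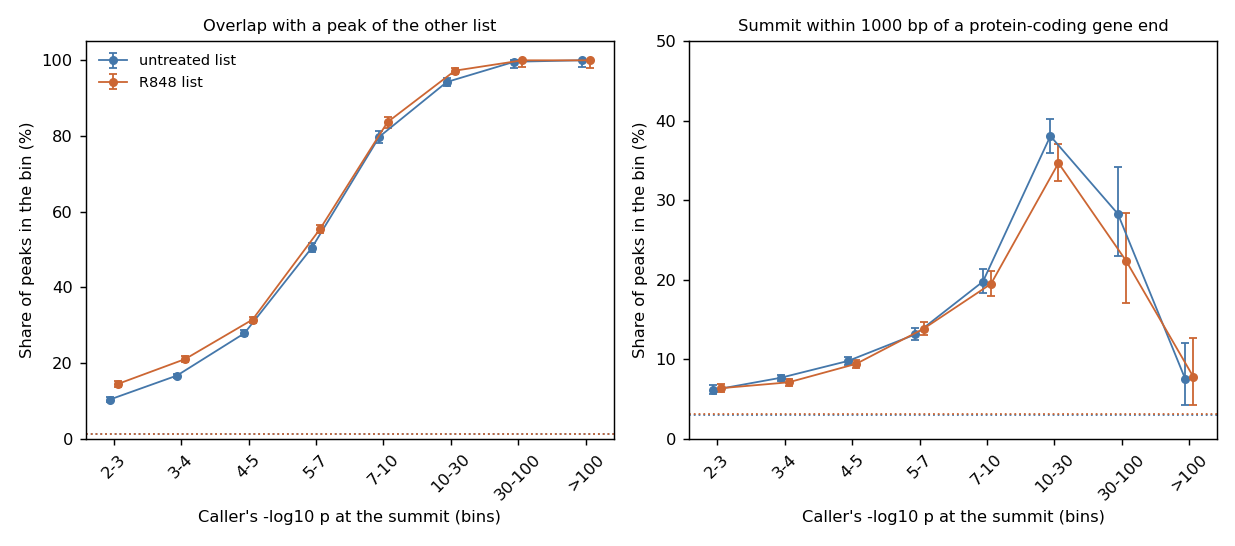
Share of peaks that overlap the other list (left) and share with a summit within 1000 bp of a protein-coding gene end (right), in %, by bins of the caller's −log10 p, for the untreated and R848 lists, with 95% exact binomial intervals as bars and random placements as dotted lines. Overlap climbs from 10.4% (untreated) and 14.5% (R848) in the weakest bin to 100% in the strongest, while the gene-end share is highest between 10 and 30 (38.1% and 34.7%).

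Among genes with a peak in the R848 list only, the highest fold over background was at Nrm, which encodes the nuclear membrane protein nurim (6.36, chromosome 17, 35861263 to 35861580, mm10). It was followed by Erbb3, a receptor tyrosine kinase (5.80, chromosome 10, 128565985 to 128566601). Next came Abhd17c, a depalmitoylating enzyme, and Gemin2, a component of the SMN complex (5.53 each). Pwp2, a factor of ribosome assembly, had 5.35, and Katna1, a microtubule-severing ATPase, and Zbtb3, a zinc finger protein, had 5.25 each. Dhrs13 and Eif4ebp2, a repressor of cap-dependent translation, had 4.97 each, and Dennd6b had 4.85. The peaks at Erbb3, Gemin2, Pwp2 and Dennd6b overlapped an untreated peak outside the window, so at these genes only the window edge separates the lists.

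Among genes with a peak in the untreated list only, Kat6b, another MYST acetyltransferase, ranked first (fold 7.29, −log10 q 17.6, chromosome 14, 21500200 to 21501427), but its peak only touched the window and overlapped an R848 peak outside it. A single peak on chromosome 13 (34002212 to 34002700, fold 5.95) lay at the adjoining ends of Ripk1 and Serpinb6a, a protease inhibitor, with no overlapping R848 peak. Another on chromosome 17 (25832717 to 25833504, fold 5.88) lay between Jmjd8 and Rhbdl1. Zfand6 (5.49), Plekho1 (5.37), Nfic, a nuclear factor I transcription factor (5.27), Bbs10, a gene of Bardet-Biedl syndrome (5.26), and Ccdc34 (5.26) completed the first 10. The peaks at Jmjd8, Rhbdl1 and Nfic, like that at Kat6b, overlapped an R848 peak outside the window.

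Of 30 inflammatory cytokines, chemokines and effectors, 5 had a gene-end peak in the untreated list and 6 in the R848 list. Cxcl2 (fold 4.08) and Tnfsf9, the ligand of the costimulatory receptor 4-1BB (3.32), had one in the R848 list only, and Cxcl3, a related chemokine (3.20), in the untreated list only. Tnf had a peak in both lists, with a fold of 2.52 and a −log10 q of 0.462 in the untreated list and a fold of 3.61 and a −log10 q of 3.34 in the R848 list. Icam1, an adhesion molecule, and the chemokine genes Ccl3 and Ccl4 also had peaks in both, at different positions in the 2 lists. The untreated peak at Ccl3 and Ccl4 was the same one, of fold 2.06, at the end of Ccl3 and inside Ccl4, which overlap in the annotation. Il6, Il1b and Ifnb1, which encode major cytokines of the Toll-like receptor response, had no gene-end peak in either list. Of 21 NF-kB family and feedback genes, 13 had a peak in the untreated list and 14 in the R848 list, and random lists of that size had a median of 6 and 5. Nfkb1 (fold 4.70), Socs3 (4.03) and Nfkbiz, an inducible nuclear IκB protein (3.04), had a peak in the R848 list only. Bcl3, a nuclear IκB protein (2.52), was among 2 members with one in the untreated list only. Relb (7.94 in the untreated list and 7.59 in the R848 list), Rel (5.49 and 6.76), Nfkbia (5.51 and 6.11) and Dusp1, a MAP kinase phosphatase (3.46 and 5.0), had peaks in both. Members with an R848 peak only minus members with an untreated peak only came to 1 for the cytokine list (percentile 81.8 among 10000 random lists matched on peak fold) and 1 for the NF-kB list (percentile 83.1), both inside the central 95%. With only peaks of q up to 0.05 in both lists, the cytokine list had 6 members with an R848 peak only and 1 with an untreated peak only (percentile 99.5). Tnf, Icam1, Ccl3 and Ccl4 are among those 6, although each had an untreated peak of q above 0.05. Where any peak of the other list counted as presence, the cytokine list had 2 and 1 (percentile 80.8), so its count depends on the threshold. The NF-kB list had 3 and 0 with q up to 0.05 in both lists (percentile 96.6), and 2 and 0 where any peak of the other list counted as presence (percentile 98.2).

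**Figure D2:**
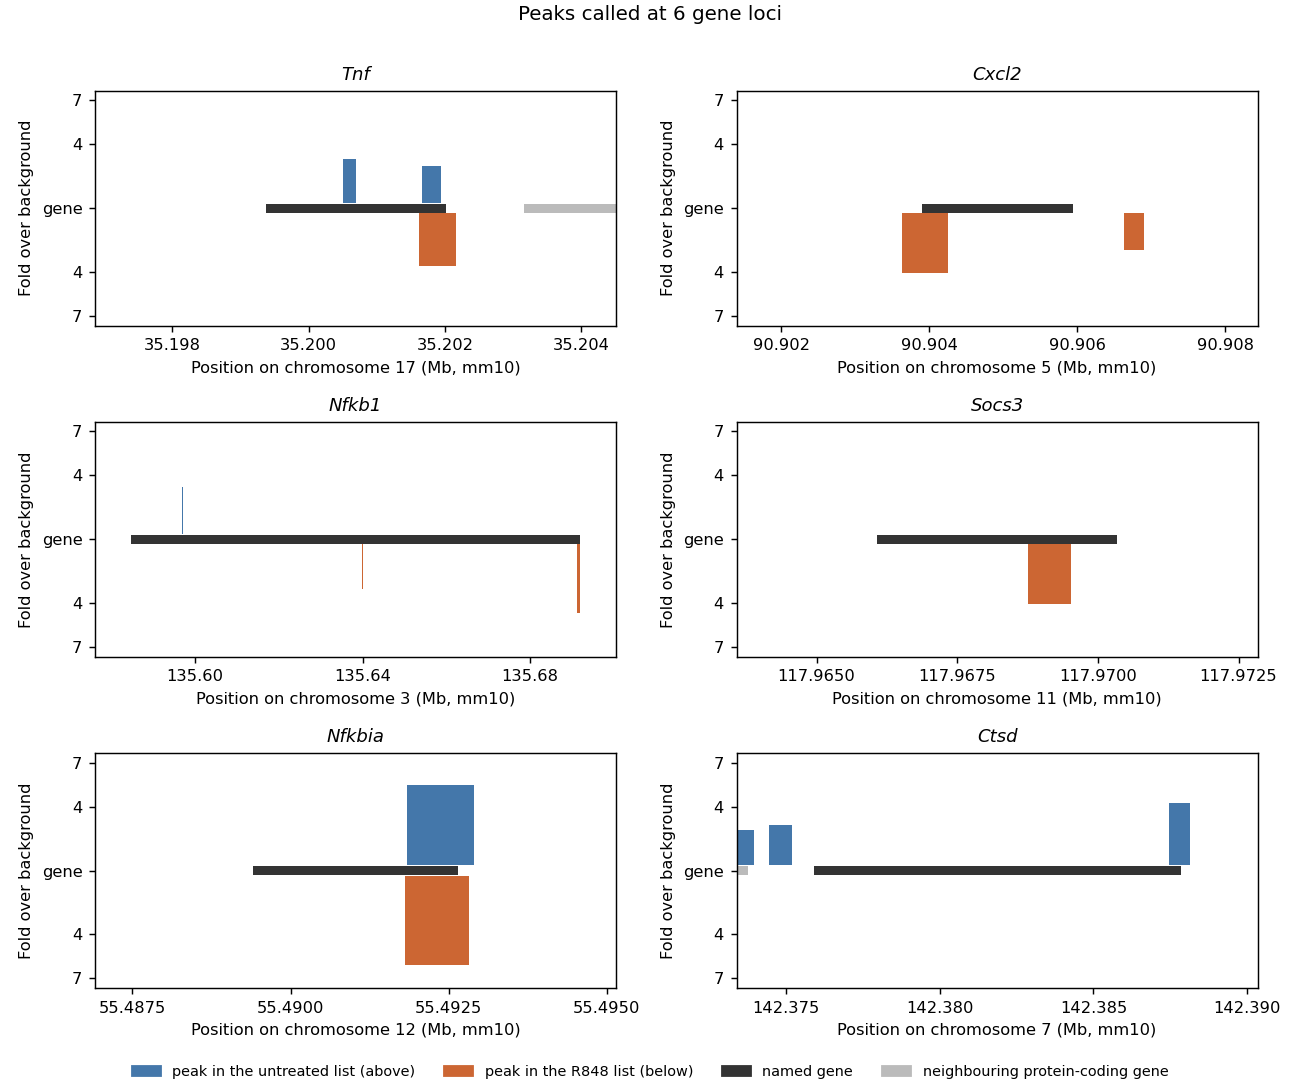
Peaks called at Tnf, Cxcl2, Nfkb1, Socs3, Nfkbia and Ctsd, with position on mm10 (Mb) on the horizontal axis and the authors' fold over background as bar height, untreated peaks above the gene and R848 peaks below it. Tnf and Nfkbia have gene-end peaks in both lists, Cxcl2 (fold 4.08), Nfkb1 (4.70) and Socs3 (4.03) in the R848 list only, and Ctsd (4.27) in the untreated list only.

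Of 20 immediate early transcription factors, 14 had a peak in the untreated list and 11 in the R848 list. Ier5 (fold 4.87), Fosb, an AP-1 subunit (2.98), and Klf4, a Krüppel-like factor (2.98), had one in the untreated list only and Maff, a small Maf protein, in the R848 list only (3.59). Klf2, Jund, Egr1 and Jun had peaks in both, with folds of 5.95, 5.90, 5.46 and 4.77 in the untreated list and 4.19, 4.07, 3.77 and 4.64 in the R848 list. Of 27 interferon-stimulated genes, 5 and 4 had a peak. Rsad2, which encodes the antiviral protein viperin (2.76), and Stat2 (2.49) had one in the R848 list only, Irf9 (3.20), the DNA-binding partner of STAT2, and Ifi35 (2.52) in the untreated list only, and Irf1 and Oasl1 in both. Of 27 Toll-like receptor signalling components, 11 and 9 had a peak. The kinase gene Tbk1 (3.43) had one in the untreated list only, as had Myd88, the adaptor downstream of TLR7 (4.35), whose peak overlapped an R848 peak outside the window, while Tab1, an activator of TAK1 (3.32), and Irf8 (3.04) had one in the R848 list only. Traf3 (5.99 and 7.50), Unc93b1, the chaperone of endosomal Toll-like receptors (5.72 and 3.59), Irak4 and Tab2 had peaks in both. Tlr7 itself, on the X chromosome, had no gene-end peak in either list. The difference between R848-only and untreated-only members was −3, −1 and −2 for these 3 lists, at percentiles 17.3, 43.0 and 35.1 of matched random lists.

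Among 26 macrophage identity genes, 9 had a peak in each library. Cebpb (fold 4.43 and 5.40) and Cebpa (5.0 and 3.32), which encode C/EBP factors of the myeloid lineage, and Ctsb had peaks in both, those of Cebpa at different positions. Spi1, which encodes the macrophage lineage factor PU.1 (2.77), and Runx1 (3.43) had one in the untreated list only, and Cd14, a co-receptor for lipopolysaccharide (3.04), and C1qb, a complement subunit (2.76), in the R848 list only. Of the 12 subunits of the MSL and NSL complexes, 7 had a peak in the untreated list and 6 in the R848 list, against a median of 3 in random lists. Kansl2 (6.18 and 3.59), Msl2 (4.81 and 5.53), Kansl3 (5.49 and 2.76) and Phf20 (4.35 and 4.15) had peaks in both and Wdr5 in the R848 list only (3.59). Kansl1 and Kat8 had a weak peak in the untreated list only (2.29 and −log10 q 0.163 each). Among 26 other histone acetyltransferases and deacetylases, 11 and 9 had a peak. Ep300 (3.89) and Crebbp (3.43), both acetyltransferases, had one in the untreated list only, as had Kat6b at the edge of the window, Hdac11 (2.76) in the R848 list only, and Kat6a, Hdac1, Kat7 and Sirt2 in both. The differences were 0, −1 and −2 members, at percentiles 66.4, 37.8 and 40.9.

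Housekeeping groups had a higher share of genes with a peak than protein-coding genes at large in both libraries, though not always beyond random lists. Those random lists were drawn from all protein-coding genes, and no control or accessibility library was analysed. For these and the other gene lists, such shares therefore do not separate KAT8 binding from cutting of open chromatin. Of 24 lysosome and autophagy genes, 16 had a peak in the untreated list and 14 in the R848 list, against medians of 7 and 6 in random lists. Wipi1 (fold 8.93 and 7.95) and Uvrag (8.82 and 6.16), both autophagy factors, Atg5 and the autophagy kinase gene Ulk1 had peaks in both, Ctsd (4.27) and Hexa, a hexosaminidase gene (3.89), in the untreated list only, and Becn1 (2.49) in the R848 list only. Cell cycle and DNA replication genes had 13 of 21 in each library, with Pcna, the replication clamp (3.66 and 5.25), Ccne1, Brca1 and Ccna2 in both and Mcm2, Mcm3, Ccnb2 and Rpa2 among 5 in the untreated list only; another 5 had one in the R848 list only. With q up to 0.05 in both lists, 6 cell cycle genes had a peak in the untreated list only and 0 in the R848 list only (percentile 5.1). Of 15 glycolysis genes, 9 and 7 had a peak, Gpi1 (6.06 and 5.64), Pkm, Eno1 and Pgam1 in both and Pfkp and the glucose transporter gene Slc2a1 in the untreated list only. Cytosolic ribosomal protein genes had 18 of 40 in each, with Rps19 (3.66 and 6.91), Rplp0, Rpl13 and Rpl14 in both and Rps20, Rpl4, Rps18 and Rpl30 in the R848 list only; another 4 had one in the untreated list only. Nuclear oxidative phosphorylation genes had 10 and 8 of 26, with Ndufv2, Ndufv1 (at different positions), Cox4i1 and Atp5b in both, and Ndufa10, Sdhb and Atp5o in the untreated list only. Random lists reached the oxidative phosphorylation counts often (percentiles 85.3 and 77.3), and the R848 count of glycolysis genes was inside the central 95% (percentile 96.7). The differences ranged from −2 to 0 members and lay inside the central 95% of matched random lists for each of these 5 groups.

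Markers of other cell types had few gene-end peaks. Of 14 lymphoid markers, none had a gene-end peak in the untreated list and Zap70, a T cell receptor kinase (fold 3.39), and Cd3d (2.76) had one in the R848 list, a difference of 2 members at percentile 95.9. Siglech, a marker of plasmacytoid dendritic cells, was the only member with a gene-end peak among 15 granulocyte and dendritic cell markers (untreated list, 2.52). None of 11 stromal markers had a gene-end peak in either list. Of 26 genes of unrelated tissues, Actn2 and Myh7 had one in the untreated list only and Syt1 and Ckm in the R848 list only, against medians of 7 and 6 in random lists. Over the whole gene and 1000 bp around it, more members had a peak. The untreated and R848 lists then had 5 and 6 stromal markers and 9 and 6 genes of unrelated tissues. Lymphoid markers had 1 and 3, and granulocyte and dendritic cell markers 2 and 2.

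**Figure D3:**
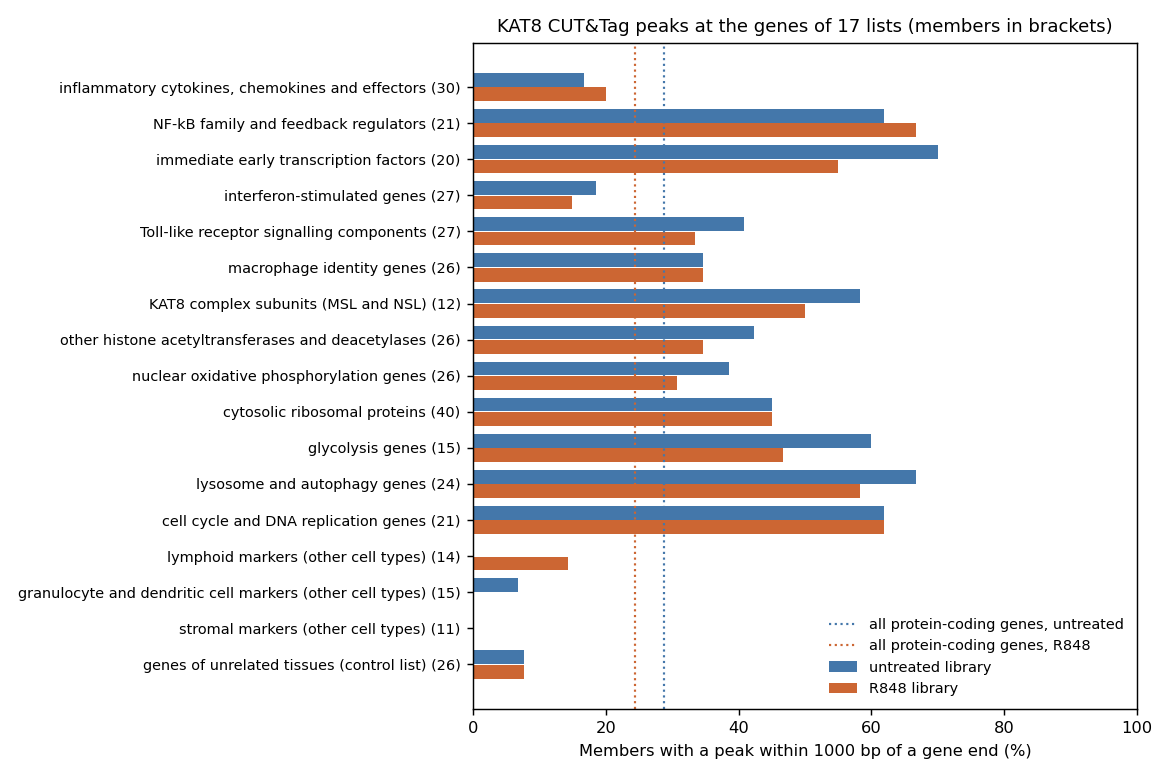
Share of each fixed gene list with a peak within 1000 bp of a gene end, in % of its members (number in brackets), for the untreated and R848 libraries, with dotted lines at the share of all protein-coding genes (28.8% and 24.4%). NF-kB, immediate early, lysosome and autophagy, and cell cycle genes stand at 55.0% or more in both libraries, and markers of other cell types at 14.3% or less.

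Peaks were concentrated at gene ends in both libraries. A summit within 1000 bp of a protein-coding gene end was found for 10.8% of untreated peaks (10.5 to 11.1) and 10.6% of R848 peaks (10.3 to 10.9), against 3.06% and 3.08% for randomly placed peaks. Shared peaks had 18.4% and 18.6% there, and peaks of 1 list only had 7.37% (untreated) and 6.13% (R848). A further 31.6% and 32.5% lay inside protein-coding genes, where random placement gave 38.3% and 38.4%, and 49.1% and 48.8% lay outside any annotated gene. Among peaks with a summit more than 1000 bp from a gene end, those with the highest fold in 1 list only lay inside Wdfy1 (untreated, 7.32, chromosome 1, 79750149 to 79750396) and inside Ksr1, a scaffold of MAP kinase signalling (R848, 6.61, chromosome 11, 79039956 to 79040240). The next in the untreated list were intergenic, on chromosome 19 at 55108 bp from Prlhr (6.41) and on chromosome 8 at 7586 bp from Cotl1 (6.38). In the R848 list the next was the Nrm peak named above, whose edge reached the window and whose summit did not.

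The gene-end peaks with the highest folds were at Wls, Sspn and Lars2, which had folds of 40.5 to 42.2 in both lists, followed by the predicted gene Gm32584 (32.8 and 35.8). Next were Gm10710 in the untreated list (19.3) and Pole4 in the R848 list (17.3), each also with a peak in the other list. The untreated peaks at Wls, Sspn and Lars2 held 1778, 1263 and 4519 overlapping fragments, against a median of 12 over all untreated peaks. Peaks were not filtered here for repeated or high-signal sequence, so these folds do not rank genes as KAT8 targets. The 5 deepest peaks of both lists were at the same places. One on chromosome 2 (98666259 to 98667336 in the untreated list) reached 20385 overlapping fragments in the untreated library and 18669 in the R848 library. The next lay in the ribosomal RNA-related sequence Rn18s-rs5 on chromosome 17, with 13081 and 11790. Of the 200 untreated peaks with −log10 p above 100, 7.50% had a summit near a protein-coding gene end, and of the 180 such R848 peaks 7.78%.

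Genes of the X chromosome carried few peaks and chromosome 13 differed most between the libraries. On X, 45 of 966 genes (4.66%, 3.42 to 6.18) had a gene-end peak in the untreated library and 40 (4.14%, 2.97 to 5.60) in the R848 library, while the autosomes ranged from 23.4% to 38.4% and from 19.2% to 33.1%. On Y, 19 (7.42%) and 14 (5.47%) of 256 genes had one. On chromosome 13, 262 of 829 genes (31.6%, 28.4 to 34.9) had a peak in the untreated library and 177 (21.4%, 18.6 to 24.3) in the R848 library, a ratio of 1.48 where the other 18 autosomes lay between 1.06 and 1.31. Peaks away from gene ends showed the same on this chromosome, with 2158 untreated and 1506 R848 peaks, a ratio of 1.43 against 1.07 to 1.28 on the other autosomes. Genes of chromosome 13 with a peak in the untreated list only included Ripk1, Serpinb6a, Pfkp and Actn2.

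**Figure D4:**
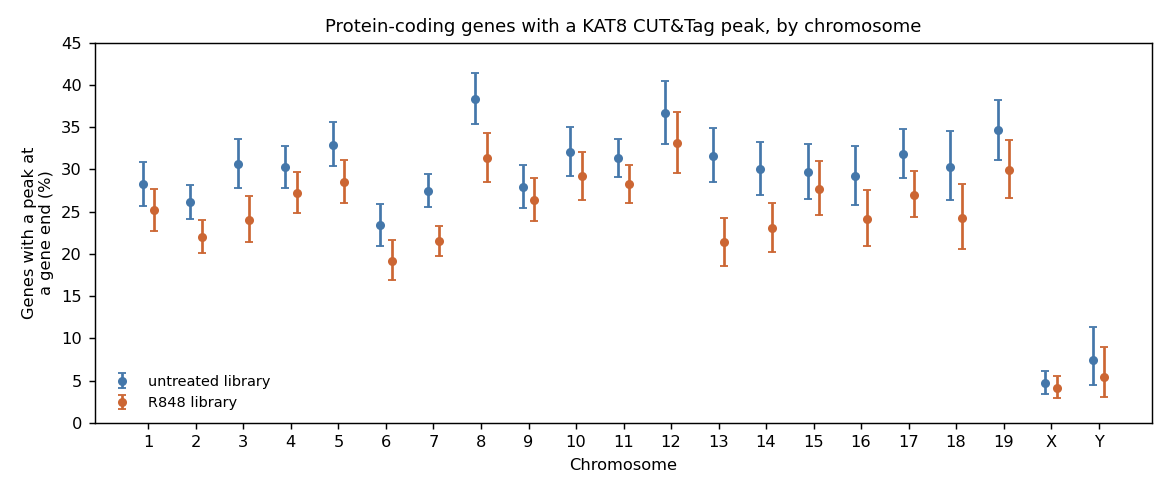
Share of protein-coding genes with a peak within 1000 bp of a gene end, in %, by chromosome, for the untreated and R848 libraries, with 95% exact binomial intervals as bars. X lies at 4.66% and 4.14%, below all autosomes in both libraries, and chromosome 13 has the widest gap between the libraries (31.6% and 21.4%).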

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

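The settings with a q of 0.05, the whole-gene window, overlap outside the window and the scaling of untreated pileups were chosen only after the data were seen. Depth limits what these lists show, since a peak of a few fragments over background in one library may miss the threshold in the other. Requiring −log10 q of at least 5 left 3286 untreated and 2646 R848 peaks, 1781 and 1774 of them shared and 1505 and 872 in 1 list only, and genes with a gene-end peak numbered 1306 and 960, with 568 in the untreated list only and 222 in the R848 list only. At −log10 q of at least 10 the values were 1291 and 1015 peaks, 839 and 836 shared, 452 and 179 in 1 list only, 572 and 386 genes, and 254 and 68 genes in 1 list only. With q up to 0.05 there were 7897 and 7890 shared peaks, 10976 and 10501 in 1 list only, 3647 and 3307 genes, and 1346 and 1006 genes in 1 list only. These counts are smaller because fewer peaks enter. Counting any peak of the other list as overlap, 1277 and 1014 peaks of −log10 q of at least 10 were shared and 14 and 1 were not, and 802 and 539 genes had a peak of q up to 0.05 in 1 list only. Overlap of 50% of each peak left 10396 shared peaks in each list. In each of these settings the untreated list had more peaks, and where given more genes, of 1 list only than the R848 list. With lists of equal length this held for genes (2206 and 1659) but not for peaks (29460 and 29467). In all, 36 values of peaks and genes, those for equal lengths among them, stayed within 1.5 times of those reported. The others came from other windows, summits within 250 bp, scaled pileups, overlap outside the window (2480 and 1535 genes) and the remaining settings.

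Differences between R848-only and untreated-only members turned for 5 gene lists, and the cause was not tested. They became 1 for Toll-like receptor components and 2 for other acetyltransferases and deacetylases with windows of 3000 bp. They became 2 for interferon-stimulated genes and 1 for glycolysis genes over the whole gene, and 1 for KAT8 complex subunits with q up to 0.05 against any peak of the other list. Of the other values for gene lists and locations, 224 stayed near those reported (counts of members inside the 95% binomial interval, differences within 1 member or 50%) and 81 moved further. Motif and sequence-content alternatives and the window at the gene's own 5′ end were not run. No paired analysis was possible because each group has 1 library and the result comes from no test.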

Other observations

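All gene families of this part, and the tests of depth, of open chromatin and of a general shortfall, were chosen only after the data were seen. Among 18 gene families and gene types compared, tRNA genes were the ones with more members in the R848 list beyond matched random lists. Of 408 tRNA genes, 61 had a peak within 1000 bp in the untreated list and 76 in the R848 list, with 18 and 33 in 1 list only, a difference of 15 where random lists gave −24 to 3. Those 33 genes rested on 21 distinct peaks and the 18 on 13, so random lists that treat neighbouring genes as separate are too narrow for this family. Zinc finger protein genes of the Zfp series went the other way, with 62 of 397 in the untreated list only and 22 in the R848 list only (60 and 23 distinct peaks), a difference of −40 where random lists gave −33 to −1. Outside chromosome 13 the zinc finger difference was −38 and the tRNA difference 17. Long non-coding RNA genes had 871 in the untreated list only and 662 in the R848 list only, a difference of −209 where random lists gave −343 to −222. Proteasome subunit genes had 11 and 3, inside the random range. Olfactory receptor genes (3.06% and 2.70% with a peak) and Hox genes (5.13% and 2.56%) carried few peaks in either library.

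The untreated list was the longer by 1.16 times, and scaling its pileups to the R848 background left 51281 of its 52001 peaks. The scaling acts only on peaks already called in the deeper library, so it does not test whether depth lengthened the list. Peaks whose summit pileup was at least 6 times the local background, a ratio without the 1 that the deposited fold adds to both terms, numbered 1804 in the untreated list and 2527 in the R848 list. That ratio takes fewer fragments at the lower R848 background (2.62 against 3.37), so the counts do not compare peaks of like significance. At −log10 q of at least 10 the order was the reverse, with 1291 untreated and 1015 R848 peaks.

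R848-only peaks slightly outnumbered untreated-only peaks at cytokine and NF-kB genes as 1 list, with 5 members against 3, and Cxcl2, Nfkb1 and Socs3 among the 5. The difference lay at percentile 90.6 of matched random lists. When a peak of 1 list only had to reach a q of 0.05, it was 4 against 1 (percentile 96.4), still inside the central 95%. For the NF-kB list alone it then lay at 98.2 (2 against 0). The difference did not shrink without the weaker calls, but with so few members a part played by calls near the threshold was not settled. With a q of 0.05 required in both lists, the joint difference was 9 against 1 (percentile 99.9). Over whole genes it lay at 98.65, and both settings were chosen after the data were seen. Lymphoid markers, with 2 against 0 (percentile 95.9), lay further out than both lists as one at any strength. Peaks shared by neighbouring members account for little of the 5 against 3, since the former rested on 2 more distinct peaks than the latter. Unequal depth would favour the deeper untreated list, the opposite of the direction seen. Since the difference lay inside the central 95%, it was too small to decide on depth. Scaling the untreated pileups to the R848 background gave a difference of 4 in place of 2 (percentile 97.4, and 97.95 for the cytokine list alone). That scaling can only remove untreated peaks, so the difference could only stay or rise, and it does not test depth. Cytokine members with an untreated peak fell from 5 to 3 under it. Ccl3 and Ccl4 share 1 weak untreated peak (fold 2.06) of the lowest pileup called, 8. The untreated peaks at Tnf, Icam1 and Cxcl3 had pileups of 10, 12 and 13. The rise therefore rested on 1 peak counted for both Ccl3 and Ccl4. With 0 control or accessibility libraries among those analysed, transposase cutting at newly opened chromatin and KAT8 binding after TLR7 stimulation both remain open.

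Genes of the X chromosome had a gene-end peak 0.154 times as often as autosomal genes in the untreated library and 0.162 times in the R848 library. Peaks away from gene ends were less scarce there, at 0.561 and 0.535 times the autosomal density, so lower coverage of X could be part of the pattern and the size of its part was not settled. Reducing all autosomal pileups by 50% left 10.4% and 8.57% of autosomal genes with a peak, and at the lowest 7.51% (untreated) and 5.28% (R848) on any autosome. The upper bound of the X share was below that value in the untreated library (6.18%) and above it in the R848 library (5.60%), so a single dose of X cannot be told apart from a true scarcity of KAT8 at X-linked genes. Peaks were also called on Y, 610 and 465 away from gene ends and at 7.42% and 5.47% of its genes, the labels used here give no sex of the animals, and no biological explanation was tested.

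Histone genes had a peak at 59 of 68 in the untreated list and 41 in the R848 list, and the 18 with a peak in the untreated list only, among them H4c9 (fold 4.96), all lay on chromosome 13, an example picked after its value was seen. Most histone genes with a peak were on this chromosome, 49 against 10 on chromosome 3. The 18 genes rested on 15 distinct peaks, so a few peaks shared by clustered genes do not account for them. By genes the difference lay at percentile 0.2, but by distinct peaks 20 of the 39 untreated histone peaks of chromosome 13 were shared, percentile 15.2 among gene-end peaks of like fold on all chromosomes and 77.5 among those of chromosome 13, which is consistent with a general shortfall of the R848 list, or one of this chromosome, and does not exclude one of histone genes. A shortfall shared evenly by all autosomes accounts poorly for the chromosome, since the untreated list held 58.9% (57.3 to 60.5) of its peaks away from gene ends against 51.6% to 56.1% elsewhere, narrowly above the 58.5% that the spread of the other autosomes allows when 1 of 19 is picked for its gap, though this was the last of 3 bounds tried and the highest upper bound of another autosome (58.0%) was not cleared by the interval. Lower coverage of chromosome 13 in the R848 library cannot be told apart from fewer KAT8 sites there, because the median pileup ratio of R848 to untreated over strong shared peaks was 0.714, under the median of the other autosomes (0.754) and above the lowest (0.699).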
